A study of Mus musculus with 2 samples.

How the data were processed

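Small RNAs of fewer than 30 bases were sequenced, per the labels, from the left cerebral cortex of female B6CASTF1/J mice at an age of 4 days. This strain is a hybrid of a C57BL/6 and a castaneus (CAST) inbred parent. The labels give 1 group of 2 biological replicates, each with a single library from a separately numbered animal, and both animals carry the same donor record. No other group was analysed here, so no comparison between conditions exists and no test between groups was run.

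The deposited values are whole-number read counts per microRNA gene, 1 table per library, with neither pooling nor normalization. The tables have no column names. Their 3 value columns were read here as uniquely mapped reads on either strand, on the annotated strand and on the opposite strand, an assumption that rests on the layout and the values, since no counter is stated. Ahead of the genes stand totals of reads that were not mapped, mapped to several places, mapped outside the genes or were ambiguous. The build was mm10 with GENCODE annotation M21, per the notes deposited with each library. The aligner, the counter, trimming and filters were not given in the sources used here. A microRNA gene is counted over its whole hairpin, so the mature products of both arms were added up. Reads that mapped to several places stood in a separate total and were assigned to no gene. This can lower the count of a gene that shares its mature sequence with a copy elsewhere. The reference strain of mm10 is C57BL/6J, and the effect of CAST variants on mapping was not tested.

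All 2202 gene IDs of the tables matched annotation M21, which supplied symbols, coordinates (1-based, mm10) and host genes. Totals that name no gene were left out of library sizes and are given as shares of all reads. Counts on the annotated strand were the main values, since adapter-ligated small RNA libraries keep the strand, and CPM, counts scaled to the same total over microRNA genes in each library, were computed here from those deposited counts. That sum was 3555469 reads in replicate 1 and 2761003 in replicate 2, so that 1 CPM is worth 3.56 and 2.76 reads. A count of 0 allows up to 3 counts, or 0.844 CPM in replicate 1 and 1.09 CPM in replicate 2. Shares of single libraries have 95% Wilson intervals. Ratios between the replicates are log2 ratios of CPM scaled with the trimmed mean of M-values (TMM), with 0.5 added to each count, and have 95% exact (Clopper-Pearson) intervals. All these intervals and limits cover counting error only, because amplified reads are not independent molecules.

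A gene was called detected at 2 CPM or more in both libraries. Agreement between the replicates was computed across genes on log2(CPM + 1) for genes at 2 CPM or more in either library, with 1000 bootstrap draws of genes. The biological coefficient of variation was the square root of the common dispersion of edgeR 4.0.16 with an intercept only. It is the spread between the libraries beyond counting error, in which animal, dissection and library preparation cannot be told apart. Its interval came from 100 bootstrap draws of genes with both libraries kept fixed, so it does not cover other animals. A chi-square test of homogeneity over genes with a summed count of 10 or more asked whether both tables hold the same library. It compares those libraries, not conditions or animals, and the number of animals rests on the labels. Genes are not replicates, so no p-value across genes is given.

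The microRNA lists, 19 in all, were fixed before the data were examined. They held neuron-enriched microRNAs, neural progenitor and brain microRNAs, oligodendrocyte microRNAs, the let-7 family, the Mir125, Mir99 and Mir100 genes that lie beside let-7 copies, the Mir29 family, the cluster around Mir17 with its paralogs, and microRNAs of microglia and leukocytes, red cells, vessels, epithelia, choroid plexus and ciliated cells, striated muscle, liver with gut and pancreas, and pluripotent cells. The others were the Mir183 cluster of sensory organs, microRNAs inside Hox clusters, the imprinted Dlk1-Dio3 cluster and the repeated cluster in an intron of Sfmbt2. Mir219a, Mir219b, Mir219c and Mir338 stood in both the progenitor and the oligodendrocyte list. Members were matched by symbol, and the stems Mir92a and Mir7a matched no gene. Mir92-1 and Mir92-2 are thus missing from the Mir17 list, and Mir7-1 and Mir7-2 from the progenitor list. The median level of the detected members of each list was ranked among 10000 random lists of as many detected genes, so that members below the detection minimum do not enter that percentile, and its median log2 ratio among 10000 random lists matched on mean expression. Both percentiles describe these libraries. Random lists drew genes singly, whereas some lists hold neighbours from 1 locus. Such neighbours may move together, which can make the percentile of a list more extreme. The median log2 ratio used members with a summed count of 10 or more.

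Named genes followed a rule fixed before the data were examined. They were the 20 genes with the highest mean CPM, up to 4 members per list with the highest mean CPM, up to 5 genes per direction with the largest ratio between replicates among those at 2-fold or more with a summed count of 100 or more, up to 5 genes with most reads on the opposite strand, and members of families with several copies where copies are described. Copies were defined by numbered symbols (an ending such as -1 or -2). The alternative was a stretch of 22 bases shared with another annotated hairpin at a place that does not overlap. Clusters for the comparison of members with and without such a stretch were genes on the same strand under 10 kb apart, with a member at 100 CPM or more. Genes that overlap another microRNA gene on the other strand and had under 10 summed counts of their own were left out of it.

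The calculations were run in R 4.3.3 and Python 3.11.15 with scipy 1.17.1. Alternative scalings of the ratios were the relative log expression (RLE) factors of edgeR and library size alone. DESeq2 1.42.0 served as an alternative for dispersion, as the square root of the median of its fitted dispersions over genes. The code was tested on simulated counts for the replicate comparison with 200 of 2202 genes changed. These were drawn from genes with a summed count of 100 or more, in random directions. Only genes with such a count were scored, so most scored genes were changed ones. Of 100 genes changed 3-fold, 94% had a ratio of 2-fold or more in the right direction, as had 95% of 100 genes changed 4-fold and 2.68% of 112 genes without a change. A coefficient of variation of 0.224 was recovered as 0.215. This simulated spread is smaller than the 0.390 found between the real libraries. The 2.68% is therefore not the rate of unchanged genes to be found beyond 2-fold in these data. Alternatives covered the detection minimum, the count column, each library alone, the denominator, the genes and pseudocount used for agreement, the scaling, the low count filter, the size rule and the definition of copies.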

Results

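MicroRNA genes were measured in the left cerebral cortex of female B6CASTF1/J mice at 4 days of age, in 1 group of 2 animals with a library each. Replicate 1 held 11686912 reads, of which 3555469 (30.4%) were counted on the annotated strand of microRNA genes. Replicate 2 held 9938361 reads, of which 2761003 (27.8%) were counted there. Reads mapped to several places made up 45.8% of replicate 1 and 41.0% of replicate 2, unmapped reads 19.3% and 25.6%, and reads mapped outside microRNA genes 4.50% and 5.63%. Values over both animals are means ± SD with n = 2, and coordinates are on mm10. Log2 ratios are of replicate 2 over replicate 1, so that values below 0 mean higher in replicate 1.

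Among counted reads, the cortex profile was led by the let-7 family, regulators known to accumulate as cells differentiate. Reads mapped to several places are left out, so genes with copies elsewhere may rank too low. None of the 20 most abundant genes shares 22 bases with a hairpin elsewhere. Mirlet7i held 10.7% ± 1.38 of microRNA counts, Mirlet7g 8.65% ± 1.06 and Mirlet7b 7.01% ± 0.646, followed by Mir99a with 5.40% ± 0.309. Of the 10 most abundant genes, 4 were let-7 members, including Mirlet7d with 2.70% ± 0.290. Mir298 (3.02% ± 0.792), Mir744 (2.45% ± 0.119), the neuron-enriched Mir139 (2.36% ± 0.663) and Mir149 (2.09% ± 0.146), and the imprinted Mir127 (2.27% ± 0.328) completed the 10. Together these held 46.7% ± 0.389 of counts. The next 10 were Mirlet7e, Mir382, Mir770, Mir487b, the endothelial Mir126a, Mir652, Mir137, Mir99b, Mir125a and Mir30d, at 2.02% to 1.07%, and the first 20 reached 62.0%. Among these 20 genes the ratio between animals was furthest from 1 for Mir487b and Mir99b. Mir487b held 2.52% (Wilson interval 2.51 to 2.54) of replicate 1 and 0.825% (0.815 to 0.836) of replicate 2, and Mir99b held 0.754% (0.745 to 0.763) and 1.77% (1.76 to 1.79).

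Among the leading genes, Mirlet7i (ENSMUSG00000065406.3) lies on the minus strand of chromosome 10 from 122985640 to 122985724, in an exon of the transcribed pseudogene D630033A02Rik. Mirlet7g (ENSMUSG00000065440.1) lies on the plus strand of chromosome 9 from 106178840 to 106178927, in an intron of Wdr82. Mirlet7b (ENSMUSG00000065564.1) lies on the plus strand of chromosome 15 from 85707319 to 85707403, in an exon of the noncoding Lncppara. Mir99a (ENSMUSG00000065530.1) lies on the plus strand of chromosome 16 from 77598936 to 77599000, in an intron of its host transcript Mir99ahg. Mirlet7e, Mir99b and Mir125a lie together on chromosome 17 between 17830188 and 17830879, within Spaca6.

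In all, 450 of the 2202 microRNA genes were detected at 2 CPM or more in both libraries, with 478 at that level in replicate 1 and 493 in replicate 2. Reads were found for 795 genes in either library. The other 1407 had none, which allows up to 0.844 CPM in replicate 1 and 1.09 CPM in replicate 2. The 75 most abundant genes held 90% of mean counts.

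Neuron-enriched microRNAs held 8.26% ± 1.56 of counts, and 15 of 18 members were detected. Mir139, Mir149, Mir137 (1.40% ± 0.0512) and Mir128-1 (1.04% ± 0.520) led the list, and the median level of its detected members lay at percentile 98.7 of random lists of detected genes, as all level percentiles are given here unless stated. The progenitor and brain list, without Mir7-1 and Mir7-2, held 2.98% ± 0.298 with 16 of 19 members detected, at percentile 91.7. It was led by Mir181d (0.866% ± 0.190), Mir181c (0.576% ± 0.0533), Mir92b (0.451% ± 0.125) and Mir181b-2 (0.448% ± 0.275). Oligodendrocyte microRNAs stood at 0.0763% ± 0.0212, with 3 of 6 members detected (Mir338, Mir219a-2 and Mir219a-1), at percentile 54.0. Copies of Mir124a and Mir9 lay far below these leading members, with Mir124a-1 at 2.51 ± 1.57 CPM and Mir9-3 at 190 ± 11.7 CPM. In these lists 11 of 18, 12 of 19 and 3 of 6 members share 22 bases with another hairpin, so that their levels are uncertain.

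The let-7 family as a whole held 32.4% ± 2.06, and all 12 members were detected. The Mir125, Mir99 and Mir100 genes, whose clusters hold let-7 copies, held 9.32% ± 0.0916 with 6 of 6 detected, including Mir100 with 1.00% ± 0.0644. The median level of the let-7 family lay above that of all 10000 random lists and that of the Mir125, Mir99 and Mir100 genes at percentile 99.99. The Mir29 family, known to rise as the cortex matures after birth, held 0.0396% ± 0.00805, with Mir29a at 229 ± 63.4 CPM, Mir29c at 132 ± 29.6, Mir29b-2 at 20.5 ± 9.92 and Mir29b-1 at 14.5 ± 2.58, and its median lay at percentile 37.2. The cluster around Mir17 and its paralogs, known from proliferating cells, held 2.18% ± 0.206 with 9 of 13 detected, at percentile 95.5. These values leave out Mir92-1 and Mir92-2, which the list did not match. Mir17 (8800 ± 1680 CPM), Mir93 (6495 ± 144), Mir106b (2934 ± 154) and Mir20a (2331 ± 478) led it. Members that share 22 bases with another hairpin, 6 of 12 in the let-7 family and 3 of 4 in the Mir29 family, are uncertain.

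The imprinted Dlk1-Dio3 cluster, maternally expressed and known from brain, held 13.7% ± 0.349 of counts with 52 of 59 members detected. Its leading members were Mir127 (chromosome 12, 109592846 to 109592915), Mir382 (1.78% ± 0.117, in an exon of Mirg), Mir770 (1.76% ± 0.310, in an exon of Meg3) and Mir487b (1.67% ± 1.20). Its median level lay at percentile 99.98 of random lists. The repeated cluster in Sfmbt2 held 0.236% ± 0.00933 with 7 of 81 members detected, led by Mir467d (1173 ± 103 CPM), Mir467e (498 ± 47.1), Mir669c (344 ± 11.2) and Mir669o (165 ± 19.9). The 7 detected members had a median level at percentile 64.2. The median percentile rank of all 81 members among all 2202 genes was 32, the shared rank of genes with no read. In that list 79 of 81 members share 22 bases with another hairpin.

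Vascular microRNAs held 2.01% ± 0.530, mostly Mir126a of endothelium (1.63% ± 0.487) with the mural cell Mir143 (0.367% ± 0.0465) and Mir145a (0.0119% ± 0.00297), and 3 of 5 were detected, at percentile 96.2. Microglia and leukocyte microRNAs held 0.115% ± 0.00554 with 5 of 7 detected, led by Mir146 (652 ± 86.9 CPM), Mir150 (361 ± 49.9), Mir155 (76.1 ± 15.3) and Mir142 (39.4 ± 12.4), at percentile 46.6. The share of that list was 0.111% in replicate 1 and 0.119% in replicate 2. The microglia, progenitor, Mir29 and muscle lists had median log2 ratios between replicates of 0.02, 0.02, -0.02 and -0.03, whose signs differed between TMM, RLE factors and library size.

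MicroRNAs of other organs held small shares of counts. Those of liver, gut and pancreas held 0.0420% ± 0.0100 with 7 of 9 detected, among them Mir375 (217 ± 110 CPM), Mir122 (70.9 ± 10.8), Mir217 (67.7 ± 14.9) and Mir194-2 (38.0 ± 13.8), at percentile 29.9. Striated muscle microRNAs held 0.00391% ± 0.00143 with 2 of 10 detected in both libraries at the chosen minimum, and Mir206 led with 24.6 ± 14.9 CPM. In that list 5 of 10 members share 22 bases with another hairpin, and the copies of Mir1a and Mir133a among them had no read, so that its share and detection are uncertain. Pluripotent cell microRNAs held 0.00377% ± 0.00159, and the 3 of 14 that were detected were Mir302d, Mir302a and Mir302b, at 14.9 ± 9.60, 11.1 ± 5.33 and 8.15 ± 4.36 CPM. Hox cluster microRNAs, which mark hindbrain and spinal cord, held 0.00748% ± 0.000637 with 2 of 6 detected, Mir10b at 66.1 ± 7.95 CPM and Mir10a at 6.05 ± 1.39 CPM. The 2, 3 and 2 detected members of the muscle, pluripotent and Hox lists had median levels at percentiles 14.3, 17 and 19.8 of random lists of detected genes. Over all members of these lists, most of them not detected, the median percentile rank among all 2202 genes was 54.6, 69.6 and 74.9. For the liver, gut and pancreas list it was 84.8. The 1407 genes with no read share percentile 32 in that ranking. Without replicate 1 the pluripotent value was 33.5, the shared rank of genes with no read in replicate 2.

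**Figure D1:**
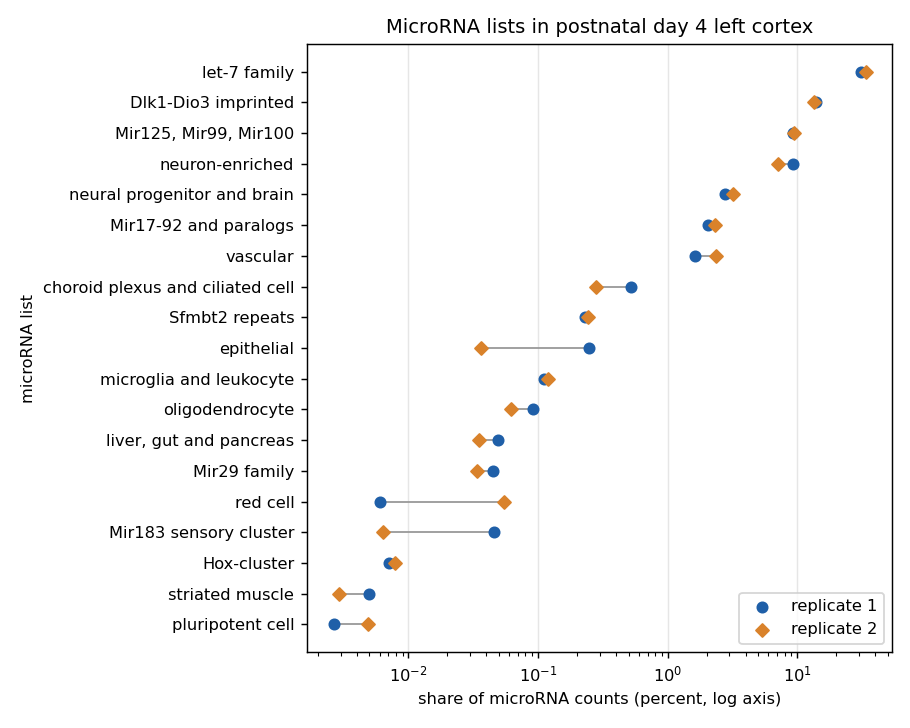
Share of microRNA counts in each of the 19 lists, in percent on a log axis, with 1 point per replicate and a line joining both. The let-7 family is highest at 31.0% and 33.9%, and the widest gaps are in the epithelial, Mir183 cluster and red cell lists.

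Epithelial microRNAs were higher in replicate 1, with 0.248% of counts (Wilson interval 0.242 to 0.253) against 0.0361% (0.0339 to 0.0384) in replicate 2. Mir200b, on the minus strand of chromosome 4 from 156055681 to 156055750 in an intron of Ttll10, had 2529 counts in replicate 1 and 19 in replicate 2 and was 98.7-fold higher (log2 ratio -6.63, counting interval -7.40 to -6.02). Its neighbours Mir429 and Mir200a were 25.3-fold and 25.1-fold higher in replicate 1, and Mir141 and Mir200c on chromosome 6 were 17-fold and 8.86-fold higher. Mir203 was 2.01-fold higher. Of the 7 members, 6 had counting intervals wholly below 0, 6 were detected in both libraries, and the median log2 ratio of -4.09 lay below that of all 10000 matched random lists. By level over both animals its detected members stood at percentile 50.7.

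The Mir183 cluster of sensory organs was likewise higher in replicate 1, at 0.0458% (0.0436 to 0.0481) against 0.00634% (0.00547 to 0.00735). Mir183 was 8.34-fold, Mir182 5.19-fold and Mir96 3.50-fold higher there, the last with an interval that spanned 0 (log2 ratio -1.81, -5.28 to 0.13). The median of -2.37 lay at percentile 0.095 of matched lists, and 2 of 3 members were detected, with a median level at percentile 44.6. Choroid plexus and ciliated cell microRNAs held 0.523% (0.515 to 0.530) of replicate 1 and 0.279% (0.273 to 0.286) of replicate 2. Mir449a was 1.77-fold, Mir204 1.71-fold, Mir34c 2.53-fold and Mir34b 2.24-fold higher in replicate 1. That list had a median log2 ratio of -0.99, at percentile 0.32, with 5 of 7 members detected and a level at percentile 83.9.

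Red cell microRNAs were higher in replicate 2, which had 0.0550% (0.0523 to 0.0579) against 0.00602% (0.00526 to 0.00688) in replicate 1. Mir451a, on the plus strand of chromosome 11 from 78073170 to 78073241, had 60 counts in replicate 1 and 1356 in replicate 2 and was 29.5-fold higher there (log2 ratio 4.88, 4.52 to 5.29). Its neighbour Mir144 was 4.44-fold higher (2.15, 1.49 to 2.91), while Mir486, in an intron of Ank1, had a log2 ratio of -0.24 (-0.66 to 0.16). Vascular microRNAs held 1.63% (1.62 to 1.65) of replicate 1 and 2.38% (2.36 to 2.40) of replicate 2, mostly Mir126a with 1.28% and 1.97%. Mir143 was 1.22-fold higher in replicate 2 (log2 ratio 0.29, 0.25 to 0.33), while Mir145a was 1.40-fold higher in replicate 1 (log2 ratio -0.49, -0.71 to -0.27). The red cell median of 2.15 lay at percentile 99.9 of matched lists, with 3 of 4 members detected and a level at percentile 34.7.

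In the other lists median ratios went in both directions. The pluripotent list had a median of 1.16 over 3 members, at percentile 97.2, the let-7 family 0.26 (percentile 94.8) and vascular microRNAs 0.29 (percentile 79.8). The other pluripotent members with reads, too few for the median, had more counts in replicate 1, led by Mir302c with 7 and 0. Medians of the neuron-enriched list (-0.17), the Dlk1-Dio3 cluster (-0.22, at percentile 0.82) and the oligodendrocyte list (-0.35) were below 0. Those of the Mir125, Mir99 and Mir100 genes (-0.10), the Mir17 cluster (-0.05), the Hox list (-0.42), liver, gut and pancreas (-0.34) and the Sfmbt2 cluster (0.05) had the same sign under TMM, RLE factors and library size.

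Outside the lists, Mir26a-2 was 20.7-fold higher in replicate 1 (912 and 33 counts), and Gm23935 (17-fold), Mir185 (9.31-fold, 487 and 3455 counts, in an intron of Tango2) and Mir3074-1 (3.99-fold) were higher in replicate 2. Mir26a-2, Gm23935 and Mir3074-1 share 22 bases with another hairpin, and their counts are uncertain. Among 308 genes with a summed count of 100 or more, 34 were at least 2-fold higher in replicate 1 and 16 in replicate 2, and 18 and 7 of these were in a fixed list. Without the epithelial, Mir183 cluster and red cell lists, left out after seeing the data, the numbers were 26 and 14. With all lists and a minimum summed count of 20 they were 50 and 39. A single library per animal gives no test of these differences.

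**Figure D2:**
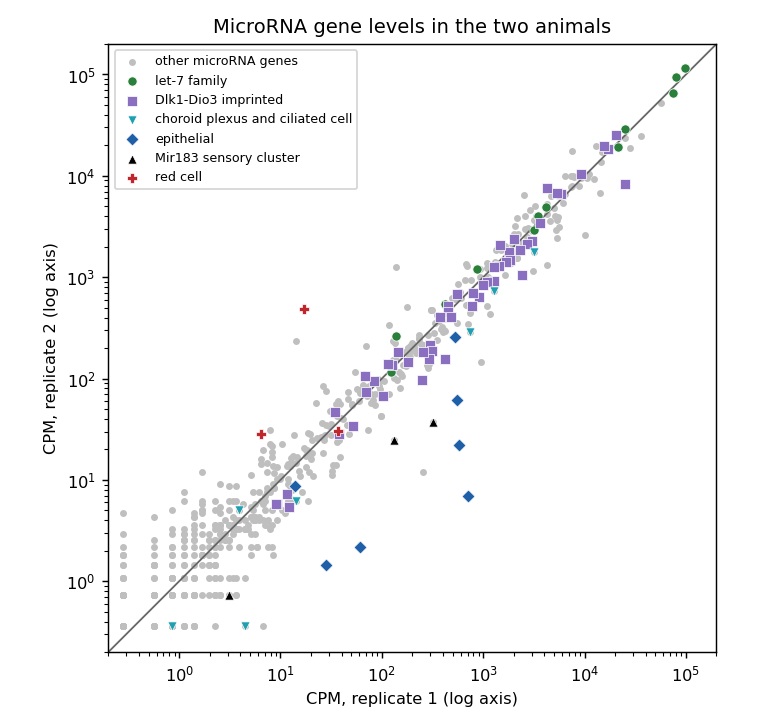
CPM of each microRNA gene in replicate 1 and replicate 2, both on log axes, with 1 point per gene that has reads in both, coloured by list, and the line of equal CPM. Epithelial and Mir183 cluster genes lie below the line and Mir451a above it, with 16.9 CPM in replicate 1 and 491 CPM in replicate 2.

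Across 521 genes at 2 CPM or more in either library, log2 CPM of the replicates had a Pearson correlation of 0.972 (bootstrap interval 0.962 to 0.979) and a Spearman correlation of 0.953 (0.937 to 0.964), and the log2 ratios had an SD of 0.94 (0.81 to 1.09). The correlation is across genes, which are not independent replicates. The biological coefficient of variation was 0.390 over 408 genes (0.343 to 0.447, from draws of genes with both libraries fixed). It was 0.323 without the epithelial, Mir183 cluster and red cell lists, an alternative chosen after seeing the data. The chi-square statistic was 168753 on 524 degrees of freedom, 322 per degree, so the tables did not hold the same library under both replicates. That the libraries came from 2 animals rests on the labels.

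Summed over genes, counts on the annotated strand were 94.2% ± 0.236 of the counts of both strands, a sum in which a read of overlapping genes counts for each strand. With each read counted once, 3555469 of 3555616 reads in replicate 1 and 2761003 of 2761133 in replicate 2 lay on the annotated strand (99.996% ± 0.000406). Among the 2138 genes with no microRNA gene on the other strand, the share was 99.995% ± 0.00045. The genes with most opposite-strand reads were Gm25927, Mir126b, Gm24083, Gm24321 and Gm25301, which overlap Mirlet7e, Mir126a, Mir191, Mir409 and Mir378a and had no read on their own strand. Gm25927 had 75779 opposite-strand reads in replicate 1 and 52940 in replicate 2, the same as Mirlet7e on its annotated strand. In all, 26 genes had more reads on the opposite strand than on their own and 100 or more over both. Each of these matched its partner's count within 1%. Without strand these reads are ambiguous, and 27 genes, among them Mirlet7e and Mir126a, lost most of their reads in that column.

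In 16 of 18 clusters of microRNA genes, a comparison chosen after the data had been seen, members with a copy elsewhere had lower counts than their neighbours. On chromosome 13, Mirlet7a-1 and Mirlet7f-1 had 482 ± 90.4 and 120 ± 4.90 CPM beside Mirlet7d at 27036 ± 2902 CPM. On chromosome 16 Mirlet7c-1 had 1041 ± 248 CPM beside Mir99a at 54007 ± 3093 CPM, and on chromosome 15 Mirlet7c-2 had 3755 ± 374 CPM beside Mirlet7b at 70082 ± 6457 CPM. Over all genes, 68.1% of the 141 with numbered symbols were below 2 CPM in a library, against 80.3% of the other 2061, a difference of -12.3 percentage points. With copies defined by 22 shared bases the direction reversed, to 93.6% of 1032 genes against 67.2% of 1170. Within the fixed lists other than the Sfmbt2 cluster the gap was smaller, with 30.6% of 49 genes against 23.9% of 155, a difference of 6.74 percentage points.

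**Figure D3:**
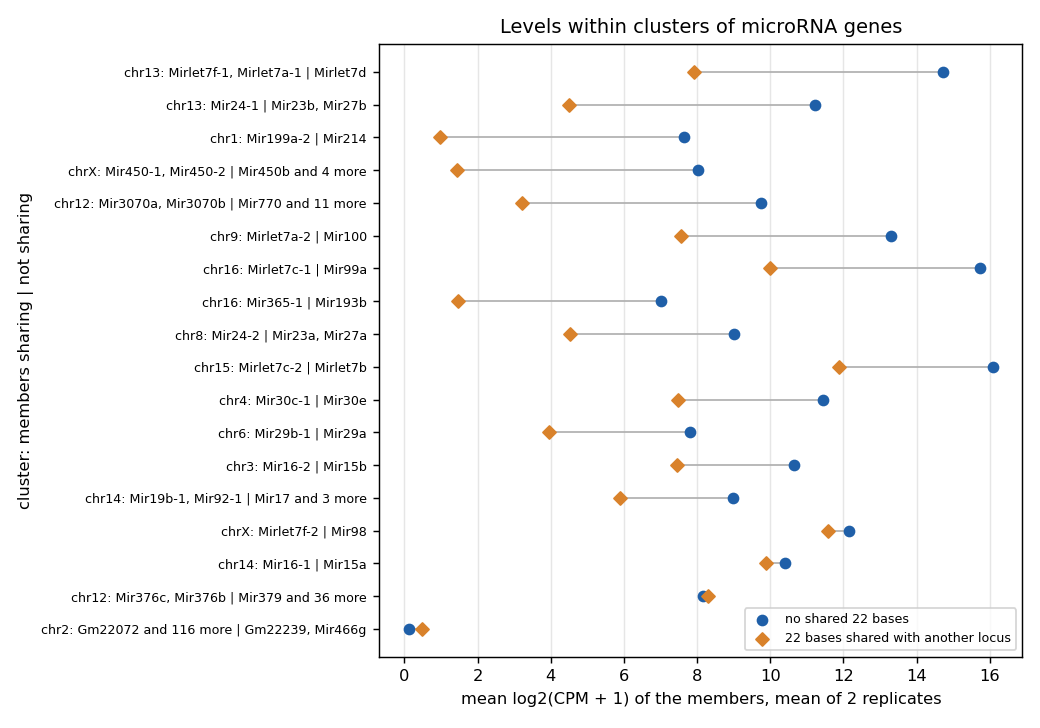
Mean log2(CPM + 1) of the members of 18 clusters of microRNA genes, averaged over 2 replicates, for members that share 22 bases with another locus and members that do not, joined by a line. The sharing members are lower in 16 of 18 clusters.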

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

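The tests on clusters and copies in this part were chosen after the data had been seen, and the shares of reads were planned. Reads mapped to several places, a total outside the gene values, made up 45.8% of replicate 1 and 41.0% of replicate 2. On the opposite strand of genes with no microRNA gene there, a column outside the main values, replicate 1 had 147 reads and replicate 2 had 130. Both are given because they are signals outside the main measurement and exceed the 3 counts that a count of 0 allows, a limit that numbers of this size pass in any case. Mir203 had 36 and 13 of them, and Mir3083 (19 and 24) and Mir5620 (13 and 20), named after their values were seen, came next.

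The reads mapped to several places are a candidate explanation for the low counts of genes with copies. Within 18 clusters, members sharing 22 bases with another hairpin were lower than their neighbours by a median log2 difference of -4.35 (SD 2.49 over clusters, 20.4-fold). Lower transcription of loci with copies is argued against, as far as neighbours share a transcript, since the sharing members were lower in 16 of 18 clusters. Differences in hairpin processing or stability between neighbours stay open and were not tested. No biological difference between groups was tested, because the design has 1 group.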

How the results depend on the processing

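The alternatives without the epithelial, Mir183 cluster and red cell lists and with each read counted once were chosen after seeing the data, and the others were planned. Over the planned and added settings, 38 values that answer a comparison stayed within the spread of the chosen setting or, for counts, within 1.5 times, 16 moved and 1 reversed. The number of detected genes stayed between 317 and 521. Each library alone gave 478 and 493 detected genes, 46.9% and 47.0% for the 10 most abundant, and 4 lists with a median level of detected members above the middle 95% of random lists in both. The share of the 10 most abundant moved to 49.7% with the unstranded column and to 42.5% without the most abundant gene in the total. The Pearson correlation was 0.980 with all genes, 0.957 at 10 CPM and 0.981 without the 3 lists, and the Spearman correlation 0.932 with all genes. The SD of log2 ratios was 1.11 with a pseudocount of 0.1 and 0.78 without the lists. The coefficient of variation was 0.323 with edgeR without the lists. From the median fitted dispersion of DESeq2 it was 0.330, a different measure from the common dispersion of edgeR. Genes 2-fold higher in replicate 2 numbered 39 at a lower minimum count of 20 and 10 at a higher one. At 1.5-fold there were 40, and 52 higher in replicate 1. The annotated strand held 89.6% of the counts summed over genes without the 10 most abundant, and 99.996% of reads with each read counted once. The copy difference reversed to 26.4 percentage points with 22 shared bases, a definition that takes in 1032 genes in place of 141. Otherwise the cause was not tested. Among values of single genes and lists, 162 stayed and 31 moved. With only these libraries behind the spread, the share in each library lies within 1 SD of the mean. The 20 gene shares and 19 list shares without either library therefore stayed by construction and say nothing on stability. In the unstranded column 5 lists lay above the middle 95%, and Mirlet7e had no reads. In that column 4 list shares moved, among them the vascular share to 0.403% and the oligodendrocyte share to 3.87e-05%. The list count was not run without the most abundant gene, which belongs to a list. Agreement, dispersion and differences need both libraries, so neither could be left out. No paired analysis was possible because the labels give a single group. Depth limits single genes near 2 CPM, and the loss of reads mapped to several places limits families with copies at any depth.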

Other observations

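All tests of explanations in this part were chosen after the result was seen, as were the genes named here outside the fixed rule and the comparison of copies. On the X chromosome, Mir1298, Mir448 and Mir1264 lie in introns of Htr2c, a serotonin receptor gene, and were 6.38-fold, 2.27-fold and 2.25-fold higher in replicate 1. Mir22 was 3.80-fold, Mir140 3.16-fold and Mir21a 2.64-fold higher there, and Mir301, Mir592 and Mir153 were 2.92-fold, 3.28-fold and 3.06-fold higher in replicate 2. Within the Dlk1-Dio3 cluster 26 members had counting intervals wholly below 0 and 16 wholly above 0. Mir487b (-1.58), Mir380 (-1.37), Mir299a (-1.35) and Mir323 (-1.19) were among the former, and Mir541 (0.87), Mir770 (0.39) and Mir127 (0.32) among the latter.

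Copies of a microRNA at separate loci had ratios between the animals that were close in most pairs and apart in others. Mir181b-1 and Mir181b-2, on chromosomes 1 and 2, had log2 ratios of 1.38 and 1.37, and Mir138-1 and Mir138-2 had 0.86 and 0.94. Mir219a-1 (0.70) and Mir219a-2 (-0.35) differed in sign, as did 3 of the 17 pairs in all, and Mir181a-1 (-0.08) and Mir181a-2 (-1.19) lay over 1 apart. Over 17 pairs of numbered copies at separate loci the median absolute difference of log2 ratios was 0.22, with the same sign in 14 pairs (82.4%), against 0.54 and 50.7% over 604 pairs of cluster neighbours without shared bases. Most of the neighbour pairs come from the Dlk1-Dio3 cluster, where a single stretch of chromosome 12 holds 37 members without copies. They do not stand for clusters in general. The pairs of both kinds are not independent, and no test was run on them.

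Epithelial and Mir183 cluster microRNAs were higher in replicate 1 together. Counting error is argued against, as 7 of 10 members had counting intervals wholly below -1. Uneven capture that depends on microRNA sequence stays open, since the median log2 ratio of -3.10 over these members comes from lists joined for their own ratios and Mir200 family members have similar mature sequences. Choroid plexus in the piece of replicate 1 is a candidate source, since the list fixed for it lay at percentile 0.32. That percentile does not allow for neighbours in the list that may move together. The list's abundant members Mir449a and Mir204 were only 1.77-fold and 1.71-fold higher, and 5 of its 7 members were detected in both animals. The epithelial list was fixed with the remark that Mir200 genes are also known from olfactory neurons, so its rise need not mean epithelium. Its members Mir203 and Mir205 were 2.01-fold and 1.54-fold higher in replicate 1, less than its other members. The interval of Mir205 spanned 0 (log2 ratio -0.62, -1.40 to 0.10). Another tissue in the piece, or reads carried over from another library, stays open, and no biological explanation was tested.

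Red cell microRNAs were higher in replicate 2, led by Mir451a. Counting error is argued against, since the counting interval of Mir451a started at 4.52 on the log2 scale. Blood left in the tissue of replicate 2 may contribute, but only 2 of the 3 abundant members had intervals above 0. Mir486 (-0.24, 131 and 84 counts) was not among them, which keeps this open. That gene overlaps Mir3107 on the other strand. Bases shared between overlapping hairpins were not looked for, so the counts of Mir486 are uncertain and weigh little either way. No biological explanation was tested.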
